A study of Rattus norvegicus with 16 samples.

How the data were processed

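The series holds growth plate RNA of female rats on 16 Affymetrix expression arrays, with RNA of 2 rats pooled per array. Groups were taken from the labels: 7 fractured femora, 7 intact contralateral femora and 2 femora of rats without fracture. The array intensities were made by the authors, who expressed each signal relative to an average of 500 per array, per the file headers and footnotes of the deposited table. This was checked on the values: the trimmed mean signal is 500.1 on 15 arrays and 500.2 on 1. A second deposited table lists 4748 probe sets with signals, detection calls and a score, the correlation of signal with age that the authors computed over all 16 arrays and over 8 right femora. Its signals equal those of the value table. Recomputed correlations, with the rats without fracture at day 0, differ from the deposited ones by at most 0.00032 and 0.00043. The table served only for comparison with the time slopes and for its detection calls.

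Signals were analysed as log2 of the signal plus 15.5, the 10th percentile of all values. Of 31099 probe sets, 57 controls were left out. A current rat gene table named 20826 probe sets with 1 symbol each, 436 with several and 9780 with none, which gave 14217 genes, and no coordinates were used. Sox9 and Pthlh are not analysed here. Probe sets were tested if their mean log2 value was above the 40th percentile, a signal of 120.2, which kept 18625 probe sets of 10424 genes. Of the probe sets in the authors' table, 91.6% of the detection calls above this limit and 20.6% below it were present.

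The fractured and intact femora of each day form a pair, since the labels call the intact femora contralateral. Deviations from the group means correlated within the pairs at −0.25, 0.48, −0.29, 0.70, 0.15, 0.30 and 0.71 from day 1 to day 42. Linear models were fitted with limma 3.58.1 in R 4.3.3 (moderated t, Benjamini-Hochberg adjusted p under 0.05). The first comparison was the mean difference of the 7 pairs, the second the slope of that difference on log2 day, and the third the slope of the pair mean on day, given per week. The p-values measure the spread between these samples. At single days, with 1 array per femur, a difference of at least 2-fold was counted without a test, and so was left minus right without fracture.

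The 26 gene lists, written by hand, cover proliferation (mitosis, DNA replication), growth plate cells (cartilage matrix, hypertrophic chondrocyte, osteoblast and bone matrix), signalling (growth hormone and IGF, BMP and TGF-beta, Wnt, FGF and Ihh-PTHrP), injury (inflammatory cytokines, interferon response), handling (immediate early, heat shock), metabolism (hypoxia and glycolysis, oxidative phosphorylation) and other cells (osteoclast, neutrophil, erythroid, B lymphocyte, T and NK lymphocyte, macrophage, skeletal muscle, adipocyte, endothelium, fibrous tissue and tendon, nerve and Schwann cell). A gene was represented by its brightest probe set. List means were tested by exact sign flips of the 7 pairs, or by exact permutation of the days for slopes, and adjusted over the 26 lists. Camera, with a preset and with an estimated correlation, and fry of limma were run beside them. List medians at single days were placed among 10000 random lists matched on mean expression.

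Genes named are those called with the largest slopes, 10 rising and 10 falling, or, where none was called, the 5 with the smallest p in each direction. To these come 10 genes named in every comparison, up to 4 members of a list with the smallest p and, at single days, the 3 largest differences in each direction among genes above the median level. Predicted gene names were passed over. A gene with several probe sets was named by the probe set with the largest change, or with the smallest p where none was called. List members and the 10 genes named in every comparison were given by their brightest probe set. The 3 comparisons, their tests, lists of alternatives and the naming rule were fixed before the data were examined. Several tests of explanations, and a list of imprinted and fetal growth genes, were chosen after results were seen, as stated with them. Alternatives were quantile normalization, median centring, a 25th percentile constant, a floor without an added constant, no filter and a 60th percentile filter, each pair left out, limma with trend and robust, array weights, no pair block, other time scales, single femora, day 0 for the rats without fracture, and other list summaries. A covariate for muscle genes and an analysis without the day 1 and day 7 pairs were added later.

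The models were tested on simulated data with 50 changed probe sets per fold and with noise drawn independently for each probe set. Limma recovered 34%, 90%, 88% and 100% at 1.5, 2, 4 and 8-fold for the first comparison, with 9 false calls. It recovered 0%, 0%, 28% and 52% for the second with 1 false call, and 0%, 2%, 56% and 88% for the third with 3 false calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and figures.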

Results

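RNA of the proximal femoral growth plate was measured after a mid-shaft fracture of the femur in female Sprague-Dawley rats that were 4 weeks old at surgery. The growth plate is the layer of cartilage near the end of a long bone in which chondrocytes divide, enlarge and give way to bone. Each of the 16 oligonucleotide arrays held RNA pooled from 2 rats. Growth plates of fractured femora were on 7 arrays and those of the intact contralateral femora on another 7, with 1 array of each at days 1, 3, 7, 14, 21, 28 and 42. The remaining 2 arrays held left and right growth plates of rats without fracture. A day therefore had 1 array per femur, and the number of arrays limits the precision of every value. The fracture was always in the left femur, per the footnotes of the deposited table, so side and fracture coincided in all 7 pairs. Mean signal per array ranged from 700.7 to 795.5, and the actin 3' to 5' signal ratio, a measure of RNA integrity, from 2.37 to 6.88.

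The first comparison asked which growth plate transcripts differed between fractured and intact femora on average over the 6 weeks, since a broken femur in a growing animal can later exceed its partner in length. Neutrophil genes were lower in the fractured femur in all 7 pairs, and macrophage genes were higher in all 7. The 10 measured neutrophil genes averaged −0.47 ± 0.32 log2 units (SD, n = 7 pairs), or 0.721 times the intact level. The 13 macrophage genes averaged 0.36 ± 0.31 (SD, n = 7 pairs), or 1.28 times. Cartilage matrix genes were lower in 6 of 7 pairs, by −0.25 ± 0.22 (SD, n = 7 pairs), or 0.839 times, while 30 mitosis genes averaged 0.015 ± 0.316 (SD, n = 7 pairs).

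None of these mean differences passed correction over the 26 lists by the exact test, which a single list could not do with 7 pairs. The exact two-sided sign-flip test gave p = 0.0156 for the neutrophil and for the macrophage list, the smallest value that 7 pairs allow, with an adjusted p of 0.203 for both. The cartilage matrix list had an exact p of 0.0312 and an adjusted p of 0.271. Camera with a preset correlation between genes gave adjusted p = 6.39e-11 for the neutrophil, 7.37e-08 for the macrophage and 5.11e-09 for the cartilage matrix list, and smaller calls for the erythroid (0.028), hypoxia and glycolysis (0.0452), osteoclast (0.0456) and T and NK lymphocyte (0.0459) lists. With an estimated correlation none of the 26 lists was called: adjusted p = 0.39, 0.398 and 0.473 for the first 3, and 0.857, 0.825, 0.825 and 0.675 for the others in that order. Fry of limma called no list in a common direction (smallest adjusted p = 0.123, neutrophil), but its mixed test, which counts members going either way, gave adjusted p = 0.0298 for the neutrophil, macrophage, cartilage matrix and FGF and Ihh-PTHrP lists.

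Across single probe sets, limma called 0 of 18625 between fractured and intact femora, with a smallest adjusted p of 0.594. At an unadjusted p under 0.05 there were 1174 probe sets, 497 higher and 677 lower in the fractured femora (589 and 550 with quantile normalization), where chance alone gives 931. The sign was the same in all 7 pairs for 382 probe sets, 171 higher and 211 lower, against 291 expected by chance. In simulated data with the spread of these pairs, the same test recovered 90% of probe sets with a 2-fold mean difference. It recovered 34% of those with a 1.5-fold difference. Those data held 50 changed probe sets at each of 1.5, 2, 4 and 8-fold, which eases the adjusted threshold. Their noise was independent between probe sets. The shares therefore do not say how often a few changed probe sets would have been called in the real pairs.

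The genes named by the fixed rule did not pass the test, each with an adjusted p of 0.73, but each had 1 sign in all 7 pairs. Higher in the fractured femora were Ch25h, a cholesterol hydroxylase, by 0.59 ± 0.10 log2 units (SE, n = 7 pairs), and Mrc1, the macrophage mannose receptor, by 0.59 ± 0.11 (SE, n = 7 pairs). P2ry6, a nucleotide receptor, differed by 0.47 ± 0.09, the phosphoprotein gene Pea15 by 0.45 ± 0.10 and Siae, a sialic acid esterase, by 0.43 ± 0.09. Lower were Camp, the cathelicidin of neutrophil granules, by −0.72 ± 0.14 (SE, n = 7 pairs), and Mrm2, a mitochondrial RNA methyltransferase, by −0.65 ± 0.10. Akr1b7, an aldo-keto reductase, differed by −0.57 ± 0.10, the peptidoglycan-binding protein gene Pglyrp1 by −0.51 ± 0.10 and the chromatin gene Dek by −0.43 ± 0.09. A brighter probe set of Dek gave −0.12 and a brighter probe set of Siae 0.03.

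In the neutrophil list 8 of 10 members were lower when adjusted over the list alone, and 0 over all probe sets tested. S100a9 and S100a8, which encode the subunits of calprotectin, were both at −0.47, with SE of 0.11 for each, and the defensin gene Np4 was at −0.67 ± 0.16 (SE, n = 7 pairs), with its lowest value, −1.70, at day 3. The macrophage list had 3 of 13 members higher when adjusted over the list alone and 0 over all probe sets. C1qb and C1qa, which encode complement chains made by macrophages, were both at 0.51 ± 0.14 (SE, n = 7 pairs). Adgre1, at 0.58 ± 0.20, did not pass over the list. In the pair without fracture, the left minus right difference was −0.16 for the neutrophil list and −0.23 for the macrophage list.

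Erythroid and B lymphocyte lists varied more from pair to pair than the neutrophil and macrophage lists. T and NK lymphocyte genes averaged −0.25 ± 0.31 (SD, n = 7 pairs; exact p = 0.0781), with Nkg7 at −0.53 and Zap70 at −0.45, both lower when adjusted over the list alone. Zap70 was negative in 6 of 7 pairs. Erythroid genes averaged −0.24 ± 0.78 and B lymphocyte genes −0.17 ± 0.46 (SD, n = 7 pairs). The inflammatory cytokine list was at 0.24 ± 0.33 (exact p = 0.109, n = 7 pairs), with Ccl2, a monocyte attractant, at 0.60 ± 0.26, and the interferon response list was at 0.037 ± 0.422. Some of these lists rest on few genes. Only 5 of 20 listed inflammatory cytokine genes, 5 of 17 T and NK lymphocyte genes and 6 of 15 B lymphocyte genes were measured. Measured means named on the array and above the filter on mean level, which can drop genes that are high on few arrays.

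**Figure D1:**
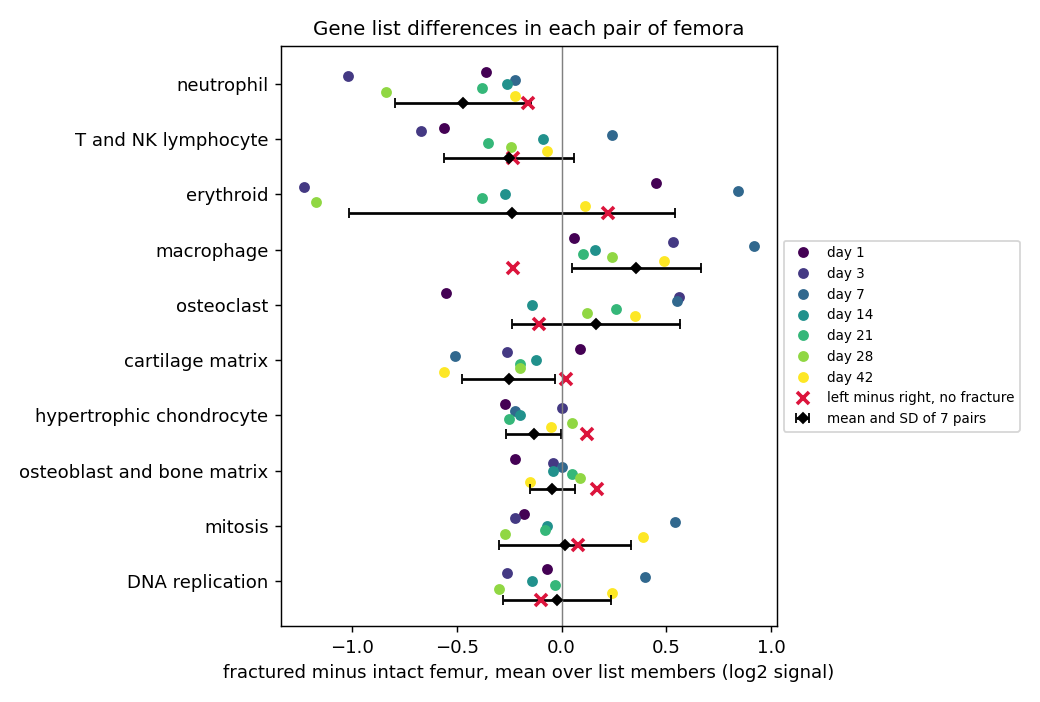
Fractured minus intact difference (log2 signal, mean over the members of each list) for 10 gene lists, with a coloured point for each of the 7 pairs, a black diamond with a bar for the mean and SD, and a red cross for left minus right without fracture. All 7 neutrophil points lie below 0 and all 7 macrophage points above it, while erythroid points run from −1.23 to 0.84.

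Among cartilage matrix genes, 14 of 15 had a negative mean difference, 9 of them at an unadjusted p under 0.05 and 1 when adjusted over the list alone. That gene was Chad, which encodes the cartilage matrix protein chondroadherin, at −0.52 ± 0.11 (SE, n = 7 pairs) and lower in all 7 pairs. Snorc (−0.37), Hapln1 (−0.31), Col9a1 (−0.27) and Acan (−0.25), all cartilage matrix or membrane components, did not pass. Col2a1, the main cartilage collagen, was at −0.22 ± 0.11 and did not pass either. Dimmer probe sets of Col2a1 gave −0.29 and 0.39. In the hypertrophic chondrocyte list (−0.13 ± 0.13, SD, n = 7 pairs, exact p = 0.0625), Ihh, the signal of prehypertrophic chondrocytes, was at −0.47 ± 0.13, Col10a1 at −0.33 ± 0.11 and Vegfa at −0.45 ± 0.20, whereas Panx3 was at 0.33 ± 0.19. None of these passed. The left minus right difference without fracture was 0.46 for Ihh, 0.26 for Col10a1 and 0.72 for Vegfa.

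Bone and proliferation genes showed no common direction. The osteoblast and bone matrix list averaged −0.045 ± 0.108 (exact p = 0.344, n = 7 pairs), with Omd at −0.42, Postn at 0.50 and Bglap, the osteocalcin gene, at −0.21 and negative in all 7 pairs. The osteoclast list averaged 0.16 ± 0.40 and ran from −0.55 at day 1 to 0.56 at day 3. Mitosis (exact p = 0.906, n = 7 pairs) and DNA replication (−0.022 ± 0.258, exact p = 0.828) lists each were higher in 2 of 7 pairs, with Top2a at 0.015 and Ccnb1 at −0.025. The sign of Top2a turned with quantile normalization and with array weights, and that of Ccnb1 without the day 1 pair (0.04). Signalling lists averaged: growth hormone and IGF −0.017 ± 0.180, BMP and TGF-beta −0.010 ± 0.092, Wnt −0.019 ± 0.169 and FGF and Ihh-PTHrP −0.098 ± 0.176 (SD, n = 7 pairs). The first 3 turned sign with a pair left out, to 0.022 (day 3), 0.012 (day 1) and 0.008 (day 42). In the FGF and Ihh-PTHrP list, Fgf9, a growth factor of skeletal development, was lower when adjusted over the list alone, at −0.38 ± 0.09 (SE, n = 7 pairs) and in all 7 pairs. Igf1 was at 0.17 ± 0.16, Igf1r at −0.18 ± 0.09 and Ghr at −0.14 ± 0.15. A dimmer probe set of Ghr gave 0.10.

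Skeletal muscle genes had the widest spread of the 26 lists, −0.14 ± 2.38 (SD, n = 7 pairs). Adipocyte genes were at 0.030 ± 1.08, heat shock genes at −0.021 ± 0.664, oxidative phosphorylation genes at −0.068 ± 0.443 and hypoxia and glycolysis genes at −0.13 ± 0.31. Fibrous tissue and tendon genes (0.13 ± 0.38), endothelium genes (−0.018 ± 0.259), immediate early genes (−0.087 ± 0.318) and nerve and Schwann cell genes (0.011 ± 0.129, 5 of 14 listed genes measured) completed the set. Without the day 1 pair, in which muscle genes were furthest apart, 2020 probe sets had an unadjusted p under 0.05 and still 0 were called.

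The second comparison asked whether the difference between the femora changed from early to late days. Limma called 0 of 18625 slopes on log2 day (smallest adjusted p = 0.822), and 1059 had an unadjusted p under 0.05, 686 positive and 373 negative, against 931 by chance (614 in all without the day 1 pair). Slpi, a protease inhibitor, had the steepest negative slope among the genes named, −0.59 ± 0.10 log2 units per doubling of the day (SE, n = 7 pairs), with a difference of 2.48 at day 1, 1.67 at day 3 and −0.93 at day 28. Wdr37 (−0.31), Tst (−0.31), Aopep (−0.28) and C8g (−0.26) also turned from positive at day 1 to negative at day 28. Fyb1, an adaptor protein gene of immune cells, had a slope of 0.34 ± 0.07, from −0.64 at day 1 to 1.36 at day 42, and Aak1 (0.31), Lgals2 (0.27), Sdc3 (0.26) and Limch1 (0.25) had slopes of the same sign. None of the 10 passed, at an adjusted p of 0.822 each. Brighter probe sets of Wdr37 (0.003), Aopep (0.08), Fyb1 (0.008), Aak1 (−0.009) and Limch1 (0.14) had smaller slopes or slopes of the other sign.

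No list's mean difference changed with the day after correction. The smallest exact permutation p over the 26 lists was 0.149, for nerve and Schwann cell genes at −0.041 per doubling of the day, with an adjusted p of 0.582. Muscle genes had a slope of −0.73 ± 0.45 (SE, n = 7 pairs; exact p = 0.157), inflammatory cytokine genes −0.10 ± 0.06 (exact p = 0.153) and cartilage matrix genes −0.064 ± 0.043 (exact p = 0.195). Without the day 1 pair, the muscle slope was 0.25. Members passed over the list alone in 3 lists, and 0 over all probe sets with limma. Igfbp2, an IGF-binding protein, had a slope of −0.36 in the growth hormone and IGF list (mean −0.045, and 0.031 without the day 1 pair). The BMP and TGF-beta list (mean 0.024) had Bmp3 (0.34) and the BMP target Id3 (0.27) positive and Bmp5 (−0.28) negative, and the inflammatory cytokine list had the chemokines Ccl2 (−0.30) and Ccl3 (−0.27) negative and the protease inhibitor Timp1 (0.17) positive.

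The third comparison asked what changed in the growth plate over the 6 weeks, in both femora together. Cytl1 and Chad were among the genes that rose, and Mest, Igf2bp3 and Tnmd among those that fell. Cytl1, which encodes a cytokine-like protein of cartilage, rose by 0.72 ± 0.11 log2 units per week (SE, n = 7 pair means), 18.9-fold over the fitted line from day 1 to day 42, and its mean signal was 1201 at day 1 and 11955 at day 42. Chad rose 5.88-fold, by 0.44 ± 0.08 per week. Mest, an imprinted gene, fell by 0.39 ± 0.04 per week to 0.202 times the day 1 level, Igf2bp3, an RNA-binding protein of fetal tissues, to 0.181 times, and Tnmd, the tendon and ligament gene tenomodulin, to 0.0921 times.

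Limma called 257 of 18625 probe sets, 32 rising and 225 falling, with a smallest adjusted p of 0.0163. At an unadjusted p under 0.05 there were 4322, 1600 rising and 2722 falling, against 931 by chance. The day 42 arrays stood apart, with a median correlation with the other arrays of 0.869 (intact) and 0.891 (fractured), against 0.917 to 0.959 for the others. The calls depended on single days: without the pair of day 1, day 3 or day 42 there were 0 rising and 0 falling, and without that of day 7, 14, 21 or 28 there were 15 and 64, 80 and 290, 5 and 55, or 3 and 32. No probe set was called without the filter on dim probe sets, from the intact femora alone, or without the day 1 and day 7 pairs, and 5 falling were called from the fractured femora alone. With the muscle list as a covariate 2 falling were called. The authors' deposited table of probe sets correlated with age held 249 of the 257, all with the same sign. Its correlations came from these same arrays, so this overlap is no independent support. All 4010 of its probe sets tested here had the sign of the slope, called or not.

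Other genes that rose were the protease inhibitor genes Mug1 (11.4-fold from day 1 to day 42 on the fitted line, adjusted p = 0.0411) and Serpina1 (5.55-fold, adjusted p = 0.0311), and the lipase inhibitor G0s2 (6.58-fold). Rcan2, a calcineurin regulator, rose 3.25-fold, Clcn4 3.16-fold, the endothelial gene Esm1 3.15-fold, Ndufb3 of respiratory complex I 3.05-fold, and Colq, the collagen tail of acetylcholinesterase, 3.03-fold. The deposited detection calls were present on 5 of 16 arrays for G0s2 on 9 of 16 for Igf2bp3, and on 11 of 16 for Serpina1, Colq and the falling gene Mlec.

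Among the falling genes were the lipoxygenase Alox15, at 0.148 times the day 1 level, the actin-binding coronin Coro1c (0.185), the endoplasmic reticulum lectin Mlec (0.186), the somatostatin receptor Sstr2 (0.19), Gnas (0.204), the angiotensin receptor Agtr2 (0.209) and Tbl1x (0.229). Brighter probe sets of 4 of these genes had smaller slopes: −0.15 against −0.42 per week for Coro1c, −0.11 against −0.41 for Mlec, −0.06 against −0.36 for Tbl1x and −0.005 against −0.39 for Gnas.

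**Figure D2:**
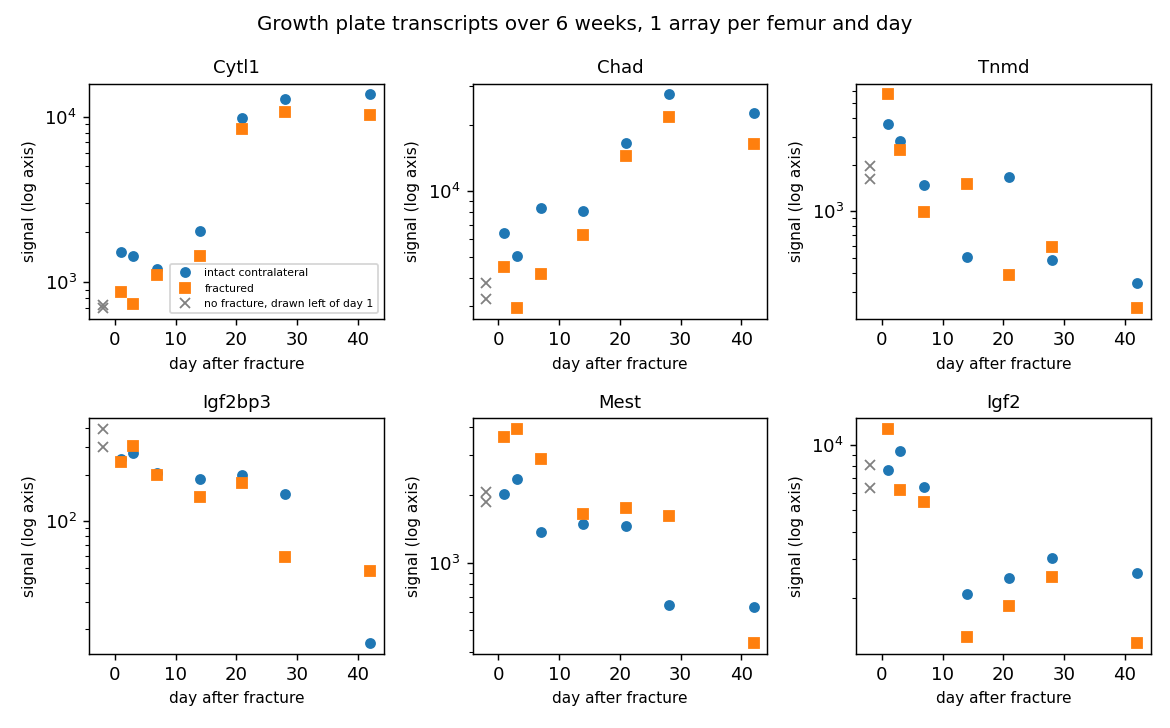
Array signal (log axis) against the day after fracture for 6 genes, with circles for intact and squares for fractured femora, 1 array each, and crosses for the 2 arrays without fracture, which have no day and are drawn to the left. Mean Cytl1 signal of the pair was 1201 at day 1 and 11955 at day 42, while that of Tnmd was 4685 and 291.

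All 30 mitosis genes had a negative slope with time. The list averaged −0.10 ± 0.05 log2 units per week (SE, n = 7 pair means), or 0.657 times from day 1 to day 42, which did not pass (exact permutation p = 0.109, adjusted p = 0.303). Of its members 12 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone: Kif20a (−0.14), Prc1 (−0.11), Plk1 (−0.20) and Ube2c (−0.15) had the smallest p. DNA replication genes averaged −0.076 ± 0.045 (exact p = 0.158, n = 7), with 24 of 27 negative and 1, the primase gene Prim2 (−0.16 ± 0.03), falling when adjusted over the list alone. Uhrf1 was at −0.25, Mcm6 at −0.13 and Lig1 at −0.12. Top2a was at −0.11 and Ccnb1 at −0.13.

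Growth hormone and IGF genes had the smallest exact permutation p of the 26 lists, 0.00694, with a mean slope of −0.046 ± 0.010 per week (SE, n = 7 pair means) and an adjusted p of 0.173. Of the 18 measured members 1 fell over all probe sets tested and 6 when adjusted over the list alone. Igfbp4, an IGF-binding protein, fell by 0.20 ± 0.04 per week (adjusted p = 0.0451). Igf2, the fetal growth factor, was at −0.39 ± 0.11 and 0.206 times the day 1 level, Socs3 at −0.16 and Igfbp5 at −0.11, these 3 falling over the list alone. Igf1 was at −0.13 ± 0.04 and also fell over the list alone, with Igf1r at −0.008 and the receptor gene Ghr at 0.14 ± 0.05. Camera with a preset correlation gave adjusted p = 1.8e-11 for the muscle list (rising), 8e-06 for oxidative phosphorylation (rising), 3.14e-05 for mitosis (falling), 0.00345 for DNA replication (falling), 0.0047 for neutrophil (rising), 0.0267 for interferon response (rising) and 0.0398 for erythroid genes (rising), and an adjusted p of 0.797 for each of these with an estimated correlation. Fry of limma called no list in a common direction (smallest adjusted p = 0.0885, growth hormone and IGF). Its mixed test gave adjusted p = 1.53e-05 for the growth hormone and IGF, Wnt and endothelium lists and 0.00237 for immediate early genes. It gave 0.00986 for BMP and TGF-beta, 0.0119 for osteoblast and bone matrix and 0.0124 for hypertrophic chondrocyte genes. The mixed test asks whether members changed at all, not whether they changed more than other genes. With limma 4322 of 18625 probe sets had an unadjusted p under 0.05, so these calls do not show changes particular to the lists.

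Wnt, BMP and endothelial genes included single falling members. Tcf7, a transcription factor of Wnt signalling, fell by 0.28 ± 0.04 per week (adjusted p = 0.0259), Eng, a TGF-beta coreceptor of endothelium, by 0.18 ± 0.02 (adjusted p = 0.0259) and the growth regulator Myc of the immediate early list by 0.26 ± 0.04 (adjusted p = 0.0253). Over the list alone, the Wnt list (−0.055 ± 0.019, exact p = 0.0365, n = 7) had 3 falling and 1 rising member, with Fzd2 at −0.14, Wnt4 at −0.15 and the Wnt inhibitor Wif1 at 0.19. The BMP and TGF-beta list (−0.030 ± 0.019, exact p = 0.163; 0.008 without the day 42 pair) had 4 falling, Bmpr2 (−0.15), Smad7 (−0.18), Tgfb1 (−0.17) and Id3 (−0.16). The endothelium list (−0.043 ± 0.012, exact p = 0.0133, adjusted p = 0.173) had 2 falling, Eng and Plvap (−0.10). The immediate early list was at −0.060 ± 0.029 (exact p = 0.0972) and the fibrous tissue and tendon list at −0.093 ± 0.043 (exact p = 0.0851), with all 12 members negative.

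Differentiation genes moved apart. In the hypertrophic chondrocyte list (−0.048 ± 0.014 per week, exact p = 0.0202, adjusted p = 0.175, n = 7) Panx3 (−0.28) and Runx3 (−0.12) fell and Vegfa (0.17) rose when adjusted over the list alone, while Ihh was at −0.19 and Col10a1 at 0.028, the latter negative (−0.06) with quantile normalization. In the osteoblast and bone matrix list (0.026 ± 0.035, exact p = 0.489, adjusted p = 0.643, n = 7; −0.035 with quantile normalization), 3 members rose and 2 fell over the list alone: Bglap (0.17 ± 0.05) and Col1a1 (0.13 ± 0.04) were among the first, Dmp1 (−0.14 ± 0.04) and Postn (−0.16 ± 0.04) the second. The slopes of Col1a1, Col2a1 (0.13) and Acan (0.053) turned to −0.01, −0.01 and −0.02 with quantile normalization. Dimmer probe sets of Col2a1 had slopes of −0.13 and 0.19. The cartilage matrix list averaged 0.048 ± 0.040 (exact p = 0.282, n = 7). With a pair left out the osteoblast list ran from 0.006 (without day 28) to 0.117 (without day 42), and passed only in the latter case (exact p = 0.00139, adjusted p = 0.0361, n = 6). The osteoclast list averaged −0.040 ± 0.037 (0.011 without the day 42 pair), with Mmp9 (−0.15) and Ckb (−0.17) falling over the list alone.

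The muscle list did not pass as a whole, and its level did not follow the day evenly, at 3.18 in the intact femur of day 7 and −0.96 in that of day 14, relative to no fracture. All 25 measured members had a positive slope, 15 rose when adjusted over the list alone, and the list averaged 0.50 ± 0.22 log2 units per week (SE, n = 7 pair means), 7.53-fold from day 1 to day 42 (exact permutation p = 0.0685, adjusted p = 0.297). Myoglobin (Mb) was 17.1-fold, Tnnc1 17.2-fold, Pgam2 14.8-fold and Acta1 6.89-fold higher on the fitted line, all over the list alone. Oxidative phosphorylation genes had 18 of 19 positive slopes, at 0.13 ± 0.07 (exact p = 0.127, n = 7; −0.032 without the day 42 pair), and neutrophil genes 9 of 10, at 0.16 ± 0.10 (exact p = 0.15), with S100a9 at 0.28 and S100a8 at 0.27.

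**Figure D3:**
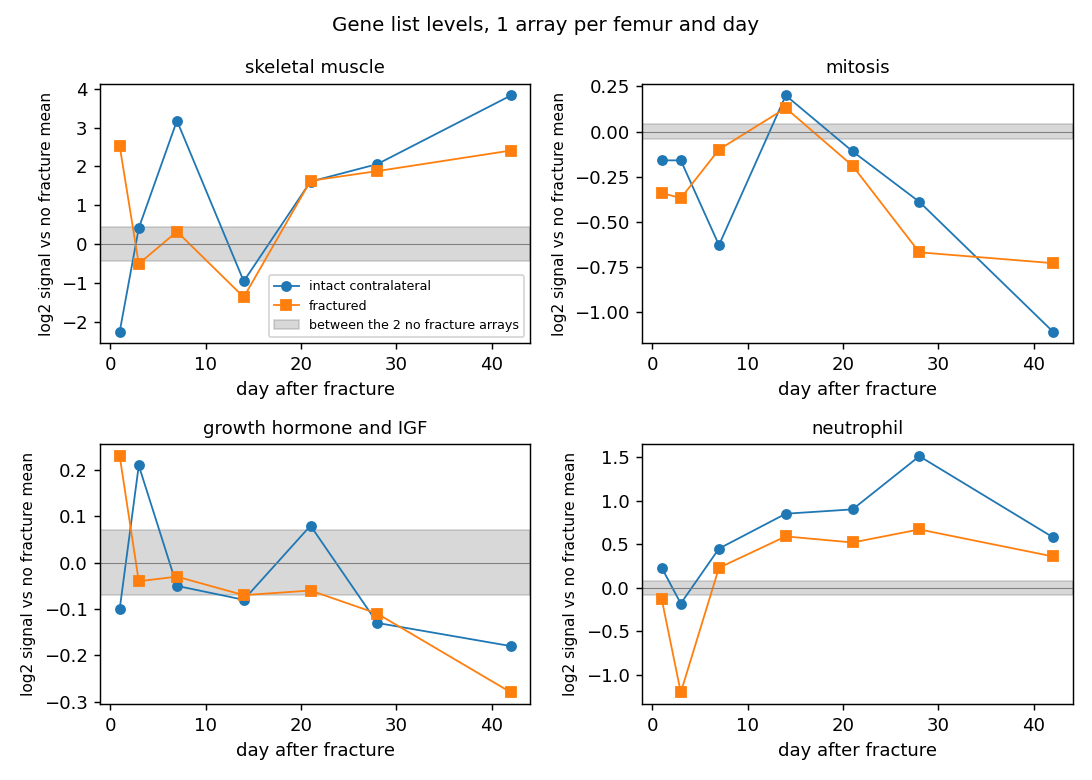
Mean log2 signal of 4 gene lists relative to the mean of the 2 arrays without fracture (grey band, left to right femur), against the day after fracture, for intact (circles) and fractured femora (squares), 1 array each. The muscle list was at −2.26 in the intact and 2.52 in the fractured femur at day 1, and at 3.18 and 0.32 at day 7.

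At single days there was 1 array per femur and no test. At least 2-fold differences between the femora were seen for 805 probe sets at day 1, 489 at day 3, 1245 at day 7, 240 at day 14, 371 at day 21, 936 at day 28 and 776 at day 42. Day 7 had the highest count with the filter on dim probe sets, and day 28 (5073, against 4836 at day 7) without it. The left and right femora without fracture differed at 714, of which 606 were higher on the left. Folds and log2 values below are of the signal plus the added constant, and signals alone, fractured against intact, are given where the lower of them was under 120.2, the level of the filter. At day 1 the muscle genes Pgam2 (3689 against 5.4), Mybpc1 (7375 against 31.6) and Myoz2 (2846 against 6.4) were higher in the fractured femur. The marrow chemokine Cxcl12 was lower (log2 −2.07), as were Enpp6 (63.7 against 314.9) and Lipc (54.0 against 236.9). At day 3 Apoe and the chemokine Ccl9 were 4.39 and 4.08 times higher, as was Cnst (279.7 against 45.3), and Ighl2 (log2 −2.65), Rhag of red cells (60.7 against 449.6) and Ankrd2 (10.3 against 132.6) were lower. At day 7 the muscle genes Myot and Csrp3 were lower in the fractured femur (log2 −5.10 and −4.76), with the kinase gene Prkaa2 (32.6 against 1371), and Gigyf1 (277.1 against 29.3), Antxr2 (321.8 against 36.7) and Yipf3 (552.8 against 94.8) were higher.

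At day 14 the tendon gene Tnmd was 2.89 times higher, as were Clcc1 (316.3 against 39.8) and Grm8 (300.1 against 47.9), and Fosb and Napsa were lower (log2 −2.86 and −2.04) with Sapcd1 (84.5 against 476.9). At day 21 Igfbp6 was lower (log2 −2.66), with Plpp3 (23.4 against 332.3) and Pla2g10 (22.5 against 231.5), and Cngb1 (443.1 against 55.2), Usp34 (464.6 against 63.8) and Cnst (494.2 against 69.7) were higher. At day 28 Acvr1 (410.6 against 29.8), Tead4 (305.8 against 40.3) and Wars1 (302.3 against 40) were higher and Bin2 (49.5 against 456.0), Gemin5 (33 against 263.4) and Pheta1 (46.8 against 286.0) lower. At day 42 sarcolipin (Sln), a muscle gene, was 11.4 times higher, with Sapcd2 (227.2 against 12.9) and Tmc4 (230.4 against 25), and the fast muscle genes Pvalb, Actn3 and Myh4 were lower (log2 −3.71, −3.50 and −3.24). Without fracture, Zfp386 and Smc5 were 8.28 and 5.87 times higher on the left, as was Trdn (583.2 on the left against 77.4), and Pdgfrb was lower on the left (log2 −1.55), with Hgh1 (94.1 against 421.1) and Dnajc11 (101.5 against 398.8).

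For 17 of these entries another probe set of the gene was the brightest, and its difference was smaller in all 17. It was −1.22 log2 units for Cxcl12 at day 1, 0.16 and 0.10 for Cnst at days 3 and 21, and 0.21, 0.69 and 0.05 for Gigyf1, Antxr2 and Yipf3 at day 7. It was 0.08 for Clcc1 at day 14, −0.14 for Usp34, −0.60 for Plpp3 and −1.59 for Igfbp6 at day 21, and 0.11, 0.02, −1.26, 0.71 and −0.16 for Acvr1, Wars1, Bin2, Gemin5 and Pheta1 at day 28. Left minus right without fracture was 0.02 for Hgh1 and −0.26 for Pdgfrb.

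Set against random lists matched on mean expression, the macrophage median lay at or above percentile 98.3 from day 3 on and at 82.2 at day 1, and the neutrophil median at or below percentile 2.5 on all 7 days. Left minus right without fracture also reached extremes, with macrophage genes at percentile 0.5, endothelium at 0 and muscle at 100, though neutrophil genes lay at 39.3. An extreme percentile in 1 pair therefore does not by itself mark an effect of fracture. The mitosis median was 0.47 at day 7 and 0.38 at day 42, both at percentile 100, but −0.36 at day 28 and −0.22 at day 3, both at percentile 0. The muscle median was 5.08 at day 1 and −3.09 at day 7, and 0.98 left minus right without fracture. The interferon response median was 0.80 at day 7, and the oxidative phosphorylation median 0.42 at day 1 and −1.04 at day 7, the pairs with the widest muscle difference. Cartilage matrix medians lay at or below percentile 0.2 from day 3 on, between −0.14 and −0.54, and at 94.6 at day 1.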

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

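The tests on the fracture itself, on scaling and on muscle tissue for the muscle genes, those on the marrow share, on side and on dilution, and the count of orders of the days at an unadjusted p, were chosen only after the result was seen, and those on the fracture itself and on the marrow share were also rewritten once after values were known. A sample far from the others of its group was looked for in 78 groups of 7, of which 6 had such a sample where chance gives about 3.9 (1 in 20). The muscle list difference was 4.78 at day 1, with −2.87 to 0.02 at the other days. The actin 3' to 5' ratio was 6.88 in the intact femur at day 28, with 2.67 to 4.28 in the other intact femora. The difference of Bglap was −0.81 at day 1, with −0.31 to −0.01 at the other days. The difference of Np4 was −1.70 at day 3, with −0.82 to −0.28 at the other days. The difference of Fgf9 was −0.03 at day 21, with −0.53 to −0.33 at the other days. The difference of Zap70 was 0.38 at day 7, with −0.77 to −0.33 at the other days.

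Muscle genes lay far apart between the femora of the day 1 pair (4.78, higher in the fractured femur) and of the day 7 pair (−2.87). Against the fracture as the whole cause, the intact femur at day 7 lay 2.74 log2 units above the higher of the 2 arrays without fracture, which differ by 0.89. Against scaling, the median difference over all probe sets was at most 2.02% of the muscle difference. All 25 members were higher in the fractured femur at day 1 and lower at day 7, which muscle tissue dissected with some samples and a response of muscle genes in single femora would both give. These 2 cannot be told apart here, since the count rests on the same genes that prompted the question.

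Neutrophil genes were lower (−0.47) and macrophage genes higher (0.36) in the fractured femur in all 7 pairs. A smaller share of marrow cells stays open: the mean of the erythroid and B lymphocyte differences lay 0.27 ± 0.28 above the neutrophil difference (SD, n = 7 pairs, exact p = 0.0625; 0.24 and p = 0.375 for erythroid, 0.30 and p = 0.0156 for B lymphocyte genes alone), and the neutrophil list had been singled out as low. Against muscle tissue, muscle genes were higher in the fractured femur in 2 pairs and lower in 5, and at no muscle difference macrophage minus neutrophil was 0.81 (95% interval 0.41 to 1.22), though both lists were singled out for their sign. Side cannot be told apart from fracture, since all fractures were on the left and 1 pair without fracture has no spread. That pair differed by −0.16 for neutrophil genes, with the sign of the fracture difference, and by −0.23 for macrophage genes, with the opposite sign. Chance among many lists could not be excluded either, as 4 of the 64 sign patterns gave at least 2 lists with 1 sign in all pairs (real 2, highest other 4), and a response of these cells to the injury stays open and was not tested.

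With time all 30 mitosis genes had negative and all 25 muscle genes positive slopes, though neither list passed. Dilution by muscle RNA would lower mitosis and cartilage matrix genes alike: the mitosis slope was −0.151 log2 units per week below the cartilage slope (exact p = 0.0895, n = 7 days), which leaves dilution open. RNA integrity, poorest by the actin ratio at day 28, might also contribute: of the 1000 probe sets with the smallest p over days 1 to 28, 73.2% ran back from day 28 to day 42, but their choice on day 28 itself favours that. The GAPDH 3' to 5' ratio, which ranged from 1.02 to 1.63, did not single out the intact femur of day 28 (1.39). Its highest value was in the fractured femur of that day. Ageing of the rats stays open and was not tested.

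For the first comparison, 9 of 64 sign patterns of the pairs gave as many probe sets at an unadjusted p under 0.05 with limma (real 1174, highest other 2458), so chance could not be excluded. For the second, 29 of 100 orders of the days gave as many (real 1059, highest other 2321), so chance could not be excluded either. Calls of these 2 comparisons decide nothing, since with a real count of 0 all 64 patterns and all 100 orders must call as many (highest other 1 in both). For the third, 2 of 100 orders, the real one included, called as many (real 257, highest other 381), so few orders reached the real count. The 100 orders are a sample of all possible ones and give this share only roughly. The calls also depended on single days, so chance is not firmly excluded.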

How the results depend on the processing

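The analyses without the day 1 and day 7 pairs and with the muscle list as a covariate were chosen only after the result was seen. For values that moved or turned, the cause was not tested, except that fewer or more probe sets or pairs entered where the filter or the pairs changed. In the first comparison limma called 0 probe sets under every alternative. Those at an unadjusted p under 0.05 were 1791 without the filter, 631 with trend and robust, 736 without the pair block with log2 day as a covariate, and 944 (without day 28) to 2020 (without day 1) with a pair left out. Leaving out the pair block changed no call. In the second comparison 0 were called throughout, with 1595 at an unadjusted p under 0.05 without the filter, 661 for early against late pairs and 614 (without day 1) to 1533 (without day 7) with a pair left out.

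In the third comparison rising and falling calls were 54 and 361 with the 60th percentile filter (181 of the 257 shared), 64 and 410 with trend and robust (247 shared), and 408 and 1142 with the rats without fracture as day 0 (255 shared). They were 0 and 0 without the filter, 1 and 2 on log2 day, 0 and 0 in the intact and 0 and 5 in the fractured femora alone, 0 and 0 without the day 1 and day 7 pairs, and 0 and 2 with the muscle covariate. With a pair left out they were 0 to 80 rising and 0 to 290 falling, with 0 and 0 without day 1, day 3 or day 42. Of the named genes, 665 of 848 settings in the third comparison kept direction and side of the threshold, 145 were weaker, 30 stronger and 8 turned. With a pair left out these were 341, 113, 6 and 2 of 462. In the first comparison 445 of 449 and 260 of 266 kept both, and in the second 159 of 159 and 119 of 119. No probe set was called in these 2 comparisons under any setting, so only the direction could have changed there.

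Turned signs of genes in the first comparison were Top2a at −0.02 with quantile normalization, −0.05 with array weights, −0.06 without days 1 and 7 and −0.08 to 0.11 with a pair left out, Igf1 at 0 without days 1 and 7, and Ccnb1 at −0.16 to 0.04 with a pair left out. For slopes with time, quantile normalization gave Col2a1 −0.01, Acan −0.02, Col10a1 −0.06 and Col1a1 −0.01. Igf1r was at 0 in the fractured femora alone, 0.02 with day 0, 0.01 with the muscle covariate and −0.04 to 0.05 with a pair left out, and Top2a at 0.05 with the muscle covariate.

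Lists in the first comparison kept their sign in 246 of 260 settings and in 158 of 182 with a pair left out. Turned were the osteoblast list at 0.02 with quantile normalization, nerve at −0.067 without the filter, −0.076 with the 60th percentile filter and −0.033 without days 1 and 7, and adipocyte at −0.044 with the 60th percentile filter, −0.024 for the median of members and −0.285 without days 1 and 7. Mitosis was at −0.014 for the median of members and −0.051 without days 1 and 7, and BMP and TGF-beta at 0.021 for the median. Without days 1 and 7 interferon response was at −0.109, oxidative phosphorylation at 0.005, endothelium at 0.042 and fibrous tissue at −0.007. With a pair left out the ranges were mitosis −0.072 to 0.063, DNA replication −0.093 to 0.024, growth hormone and IGF −0.073 to 0.022, BMP and TGF-beta −0.03 to 0.012, Wnt −0.066 to 0.008, interferon −0.108 to 0.099, immediate early −0.146 to 0.008, heat shock −0.233 to 0.143, oxidative phosphorylation −0.156 to 0.08, muscle −0.963 to 0.311, adipocyte −0.333 to 0.191, endothelium −0.066 to 0.055 and nerve −0.016 to 0.05.

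For slopes of lists with time, quantile normalization gave −0.005 for cartilage matrix and −0.035 for osteoblast genes. With a pair left out 0 to 1 lists passed (osteoblast genes without day 42), and the ranges were −0.08 to 0.011 for osteoclast, −0.041 to 0.008 for BMP and TGF-beta and −0.032 to 0.164 for oxidative phosphorylation genes. In the second comparison nerve genes were at 0.01 without the filter and 0.026 with the 60th percentile filter, muscle genes at 0.022 without days 1 and 7 and −0.94 to 0.251 with a pair left out, and growth hormone and IGF genes at 0.048 and −0.076 to 0.031. Probe sets at least 2-fold apart at days 1, 3, 7, 14, 21, 28 and 42 and left to right were 3564, 3310, 4836, 3152, 3788, 5073, 4537 and 3411 without the filter, and 439, 198, 619, 31, 61, 307, 224 and 370 with the 60th percentile filter. With a 25th percentile constant they were 274, 88, 185, 543 and 445 at days 3, 14, 21, 28 and 42, which shows how far signals near background set these counts.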

Other observations

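The list tested here was written only after the result was seen that Mest and Igf2bp3 were among the steepest falling genes and that Igf2 fell over its list. Mest and Igf2 are imprinted genes of fetal growth, and Igf2bp3 binds Igf2 RNA, so a wider decline of imprinted and fetal growth genes in the ageing growth plate is a candidate explanation. Of 20 other such genes 13 were measured, with a mean slope of −0.104 log2 units per week (exact permutation p = 0.0159, n = 7 days), or 0.656 times from day 1 to day 42, and 12 of 13 slopes were negative. Plagl1, a transcription factor of the imprinted gene network, fell by 0.32 ± 0.04 per week to 0.274 times (adjusted p = 0.0225), and the cell cycle inhibitor Cdkn1c by 0.22 ± 0.04 to 0.414 times (adjusted p = 0.0369). Peg12 (−0.21), Nnat (−0.21) and Ndn (−0.18) fell over the list alone. The others did not pass over the list: Grb10 and Sgce were at −0.09, Dlk1 at −0.06 and Igf2bp2 at −0.04. H19 and Ezh2 were at −0.03, Impact at 0 and Slc38a4 at 0.12. The mitosis list had a similar mean slope (−0.103), so a decline particular to imprinted and fetal growth genes is not shown.

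With a pair left out the mean slope of the imprinted and fetal growth list was −0.118 to −0.088. Its exact permutation p was 0.131 without day 42, 0.0528 without day 1 and 0.05 without day 3. Dilution and RNA quality were not tested for this list, which remains a hypothesis from the same data.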
